A study of Bos taurus with 10 samples.

How the data were processed

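Right ventricular tissue was collected after death and frozen, and total RNA was labelled with biotin and hybridised to Affymetrix Bovine GeneChip arrays, per the labels' protocols, with 1 array per calf. The deposited tables held log2 expression values, 1 per probe set and calf, and the authors obtained them with RMA (background correction, quantile normalization and summary over the probes of a set), per the submitters' processing notes. The software, its version and the probe set definitions behind RMA were not given in the sources used here. RMA shares information between all arrays and forces their distributions together, so a shift of all transcripts in one direction would be removed, and differences near the top of the range, up to 14.4, can be compressed. The 2 deposited tables were equal in every shared cell, with a largest difference of 0, so 1 was used. It held 24128 probe sets, of which 112 were Affymetrix controls and 24016 were tested.

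Each calf was assigned to its group by the title and group label, and calf numbers served as replicate names. The 5 control and 5 hypoxia calves share no numbers, so nothing was paired. Each calf is a separate animal. No 2 arrays held identical values, and Pearson's r between arrays, taken across probe sets that are not independent replicates, lay between 0.974 and 0.993. The labels give no batch. Scan dates were not used here.

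Of the tested probe sets, 13292 had 1 gene symbol in the platform annotation, 86 had several and 10638 had none. Of the first, 13263 had an Entrez identifier in the cattle reference table of assembly ARS-UCD2.0, and 0 symbols changed through it. Probe sets with several symbols or none were tested but not named, and 236 of the probe sets that passed had no single symbol. These left 9155 genes, 2913 of them with more than 1 probe set. A gene was represented by its brightest probe set, the one with the highest mean over all 10 arrays. By this rule 335 genes passed, against 376 that passed on any probe set. Of 106 such genes with several probe sets, 27 passed on every probe set and 88 had the same direction on every probe set. One gene, FGF1 with 12 probe sets, passed in opposite directions on different probe sets. No genome build is named for the probe sets, so no coordinates are given.

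Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), with 1 coefficient for hypoxia minus control and Benjamini-Hochberg adjustment over all 24016 probe sets, at an adjusted p of 0.05. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, on 1 probe set per gene against all other named genes, with adjustment over 40 lists of 25 pathways and 15 cell types. Camera was also run with an estimated correlation. Beside it, members that passed over all probe sets were counted, and members were counted again after adjustment over the list alone. The 3' minus 5' values of control probe sets and the list means of cell type markers, 21 measures in all, were compared by an exact two-sided permutation test over all assignments of the calves, which cannot give a p below 0.00794. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

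The test, its threshold, the 40 gene lists, the genes to be named and the alternatives were fixed before the data were examined. Named genes were the 10 largest increases and the 10 largest decreases among genes that passed, 8 cardiac and hypoxia genes whatever their result, and up to 4 members with the smallest p of each list described. Members beyond these (CDK1, CCNB1, TGFB2, COL12A1, COL1A2, COL3A1 and UCP3) were chosen after their values were seen. The fits of atrial markers without NPPA and of T lymphocyte markers without control calf 176 were also chosen after the data were seen. The atrial and adipocyte lists were added to the lists described after their values were seen. Of the 8, NPPB and MYH6 have no probe set with their symbol here and were not analysed. Alternatives covered the scaling of arrays, a filter on dim probe sets, the variance model, array weights, the test, a block for the run of calf numbers, the threshold, the choice of probe set per gene, the set test and leaving out each calf.

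The number of arrays limits the precision. The procedure was tested on simulated data with the spread of the real arrays and 200 changed probe sets among 24016 in each of 5 runs. It found 30.7% of changes of 0.5 on the log2 scale, 83.0% of changes of 1 and 99.4% of changes of 2, and 3.27% of the probe sets it called were false. Camera found 20 of 20 shifted lists and called 0 of 380 unshifted ones, with members simulated as independent. Each simulated list held 30 genes, and all members of a shifted list moved by 0.5 in 1 direction. Among the real lists that passed, only the cell cycle list had a median that large, 0.56. Values of different probe sets were drawn independently throughout. These rates therefore do not carry over to real lists with smaller, mixed or correlated changes.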

Results

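Right ventricular tissue from 10 male Holstein calves was profiled on the Affymetrix Bovine GeneChip, an oligonucleotide array that reads each transcript with a group of short probes called a probe set. The 5 control calves were kept at ambient pressure at 1525 m. The 5 hypoxia calves, titled PH calf in the labels, were kept in a low-pressure atmosphere equivalent to 4570 m. Both conditions lasted 14 days and began between postnatal days 3 and 7. Low oxygen narrows the small arteries of the lung and raises the load on the right ventricle, and the comparison asked how gene expression in this chamber differed after such exposure. Values were log2 expression, and differences are given as hypoxia minus control ± SE with n = 5 calves per group. Array medians lay between 5.48 and 5.54. The first principal component held 30.4% of the variance and separated the groups (exact two-sided permutation test, p = 0.00794, the smallest that 5 against 5 calves can give). Hypoxia calves 199 and 178 lay farthest from the controls along it, with scores of 46.1 and 34.4 against 9.79 to 13.9 in the other hypoxia calves.

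SPP1 and FABP7 had the largest increases in hypoxia among the genes that passed. SPP1, the secreted matricellular protein osteopontin, rose by 3.77 ± 0.75 (13.7-fold; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0248), from 5.08 ± 1.20 (SD) in controls to 8.85 ± 1.60. FABP7, a fatty acid binding protein, rose by 3.26 ± 0.28 (9.57-fold, adjusted p = 0.00113), and SERPINE2, a secreted serine protease inhibitor, rose by 2.40 ± 0.39 (adjusted p = 0.0123). TNFRSF12A, the receptor for the cytokine TWEAK, rose by 2.52 ± 0.57 (adjusted p = 0.0427) and passed on 2 of its 2 probe sets. CD5L, a protein secreted by macrophages, rose by 2.23 ± 0.42, and the chemokine CXCL10 rose by 2.11 ± 0.31. The mitotic genes CCNB2, UBE2C, CENPF and CKAP2 made up the rest of the 10 largest increases, with differences of 3.00 ± 0.49, 2.26 ± 0.39, 2.10 ± 0.24 and 2.03 ± 0.25. CENPF passed on 1 of 2 probe sets and CKAP2 on 1 of 3, and the means of their probe sets differed by 1.07 and 0.99. Of these 10 genes, 7 passed with each calf left out in turn. SPP1 did not pass without control calf 177 or 181 or without hypoxia calf 178, 192 or 199 (highest adjusted p = 0.0686, with differences of 3.42 to 4.41 over all calves left out), TNFRSF12A did not pass without any 1 of those calves or hypoxia calf 204 (highest adjusted p = 0.0952) or with another variance model (adjusted p = 0.0612), and CD5L did not pass without control calf 177 or 181 (highest adjusted p = 0.0538).

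SLC51B and IGSF10 had the largest decreases among the genes that passed. SLC51B, a subunit of an organic solute and steroid transporter, fell by 2.47 ± 0.30 on the log2 scale (5.53-fold, adjusted p = 0.00473), and PLIN2, the coat protein of lipid droplets, fell by 1.63 ± 0.26 (3.09-fold, adjusted p = 0.0124). The aldo-keto reductase AKR1C4 fell by 1.65 ± 0.29 on its brightest probe set but passed on only 1 of 6, and the mean of its probe sets differed by -0.56. IGSF10 fell by 2.25 ± 0.22 (adjusted p = 0.00174), and DDIT4L, an inhibitor of mTOR signalling, fell by 2.03 ± 0.38. LRFN5, ASB12, MAPK10, TCEA3 and NTRK2 fell by 1.80 ± 0.34, 1.46 ± 0.29, 1.45 ± 0.23, 1.41 ± 0.19 and 1.41 ± 0.22. NTRK2, the receptor for brain-derived neurotrophic factor, passed on 2 of 2 probe sets. Of these 10 genes, 7 passed with each calf left out in turn. DDIT4L and LRFN5 did not pass without control calf 181 (adjusted p = 0.0588 and 0.0562), and ASB12 did not pass without control calf 177 or 180 or hypoxia calf 178, 192, 199 or 204 (highest adjusted p = 0.0625).

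**Figure D1:**
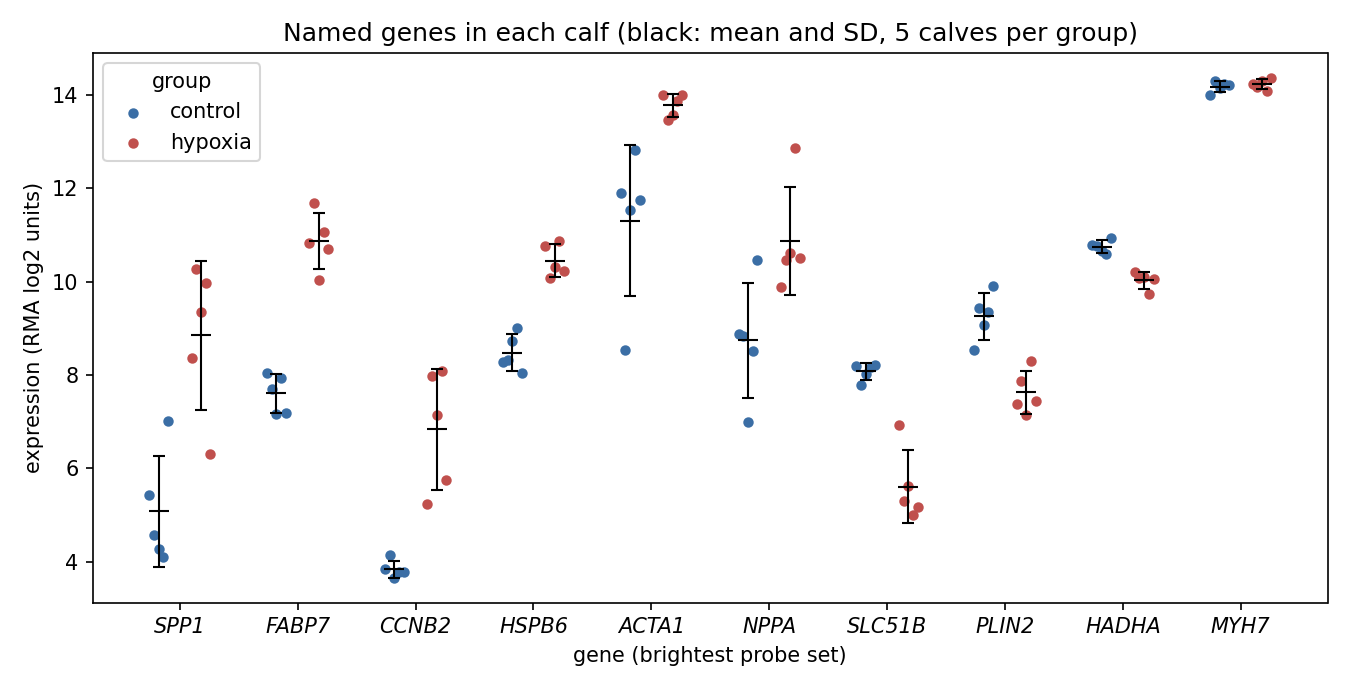
Expression of 10 genes in each calf in RMA log2 units, with blue points for 5 control calves, red points for 5 hypoxia calves and black bars for the mean and SD. SLC51B lay between 7.78 and 8.21 in controls and between 5.01 and 6.93 in hypoxia, whereas MYH7 lay near the top of the array's range in every calf.

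In all, 652 of 24016 probe sets passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 396 higher and 256 lower in hypoxia. Of these, 143 were at least 2-fold higher and 40 at least 2-fold lower. With 1 probe set per gene, 335 of 9155 named genes passed, 199 higher and 136 lower. The count of probe sets was 288 without control calf 177, 241 without control calf 181, 361 without hypoxia calf 178, 403 without hypoxia calf 192, 348 without hypoxia calf 199 and 396 without hypoxia calf 204, and it was 155 without hypoxia calves 178 and 199 together. The calf numbers fall into a lower run of 4 control and 2 hypoxia calves and an upper run of 1 control and 3 hypoxia calves. With the run as a block 217 probe sets passed, with 31 passing in the lower run alone and 0 in the upper run alone, where 2578 had an unadjusted p under 0.05. The block ended 22 of the 50 calls on named genes (adjusted p = 0.0508 to 0.108), those on TNFRSF12A, UBE2C, CD5L, DDIT4L, LRFN5, ASB12, ANKRD1, DES, P4HA1, P4HA2, ACOT2, PGK1, C1R, GUCY1B1, SQLE, CYP51A1, INSIG1, AQP1, PDGFRA, PI16, MFAP4 and AGPAT2, with no change of sign. A test per probe set without limma's sharing of variance passed 0 probe sets after the same adjustment, with 3560 at an unadjusted p under 0.05, among them all 652.

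Many genes that drive cell division were higher in hypoxia. Of 40 measured genes of the cell cycle and mitosis list, 16 rose and 0 fell (23 higher and 0 lower when adjusted over the list alone). The median difference was 0.56, or 1.47-fold. KIF23, a motor protein of cytokinesis, rose by 1.63 ± 0.19 (limma, adjusted p = 0.00367), NDC80, a kinetochore protein, by 1.22 ± 0.15 and CKS2, a binding partner of cyclin-dependent kinases, by 1.95 ± 0.27. CDK1, the kinase that starts mitosis, rose by 1.85 ± 0.28 and its partner CCNB1 by 1.14 ± 0.25. The list mean was 5.83 ± 0.07 (SD) in controls and 6.62 ± 0.30 in hypoxia, and every hypoxia calf lay above every control calf, with 6.28 the lowest hypoxia value and 5.92 the highest control value. The list passed limma's camera test with a preset correlation (adjusted p = 9.19e-16), with adjusted p = 0.337 with an estimated correlation.

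Extracellular matrix genes were shifted upward in hypoxia. Of 57 measured genes, 8 rose and 0 fell (22 higher and 3 lower when adjusted over the list alone), with a median difference of 0.45. LOXL1, an enzyme that cross-links elastin, rose by 1.61 ± 0.27 (limma, adjusted p = 0.0133), and the small proteoglycan BGN rose by 1.10 ± 0.19 on the brighter of 2 passing probe sets. P4HA1 and P4HA2, the catalytic subunits of collagen prolyl hydroxylase, rose by 0.86 ± 0.15 and 0.77 ± 0.15. The growth factor TGFB2 rose by 1.76 ± 0.34 and the collagen COL12A1 by 1.82 ± 0.42. The major fibrillar collagens did not pass, with differences of 0.10 ± 0.26 for COL1A1 (95% interval -0.48 to 0.68), 0.16 ± 0.18 for COL1A2 and 0.07 ± 0.18 for COL3A1. The list passed camera (adjusted p = 4.14e-07), with adjusted p = 0.641 with an estimated correlation. Without hypoxia calves 178 and 199 its median was 0.26 (camera adjusted p = 0.000212). Without control calf 177 or 181 the call on P4HA2 ended (adjusted p = 0.0538 and 0.0588).

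Fibroblast markers did not move as a group. Of 18 measured markers, 2 rose and 2 fell (2 higher and 4 lower when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.934). The intermediate filament gene VIM rose by 0.86 ± 0.14 (limma, adjusted p = 0.0123) and PI16, a marker of adventitial fibroblasts, rose by 1.71 ± 0.33. PDGFRA, a growth factor receptor of fibroblasts, fell by 0.89 ± 0.17 and passed on 1 of 3 probe sets, whose mean differed by -0.23 (adjusted p = 0.156), and MFAP4, a microfibril protein, fell by 0.82 ± 0.19. PI16 did not pass without control calf 181 or hypoxia calf 178, nor PDGFRA without control calf 177 or 181 (highest adjusted p = 0.0549 and 0.0596). MFAP4 passed without control calf 177 or hypoxia calf 173 but with no other single calf left out (highest adjusted p = 0.114), nor with array weights (adjusted p = 0.0647).

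Genes of fatty acid oxidation were shifted downward. Of 40 measured genes, 7 fell and 0 rose (15 lower and 1 higher when adjusted over the list alone), with a median difference of -0.24. HADHA, a subunit of the mitochondrial trifunctional protein, fell by 0.72 ± 0.11 (limma, adjusted p = 0.00931), and SLC25A20, the carnitine and acylcarnitine carrier of the inner mitochondrial membrane, fell by 0.81 ± 0.12 on the brighter of 2 passing probe sets. UCP2 and UCP3, mitochondrial uncoupling proteins, fell by 0.90 ± 0.15 and 1.33 ± 0.28, and ACOT2, a mitochondrial acyl-CoA thioesterase, fell by 0.77 ± 0.16 but passed in only 2 of the 10 fits that left out a calf. As a group these genes passed camera (adjusted p = 1.09e-04), with adjusted p = 0.641 with an estimated correlation, and its median was -0.08 without hypoxia calves 178 and 199 (camera adjusted p = 0.00775). None of 76 measured genes of oxidative phosphorylation passed over all probe sets, and 0 did when adjusted over the list alone. Their median difference was -0.05, and the list did not pass (camera adjusted p = 0.128), except without hypoxia calf 192 (median -0.07, adjusted p = 0.0459) and with the mean of all probe sets of a gene (median -0.09, adjusted p = 0.0159). The median was closer to 0 without control calf 176 (-0.02, adjusted p = 0.640), with array weights (-0.02, adjusted p = 0.748) and without hypoxia calves 178 and 199 together (-0.006, adjusted p = 0.948). The mean of the oxidative phosphorylation list was 12.4 in controls and 12.3 in hypoxia, a bright range where differences can be compressed.

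Targets of hypoxia-inducible factors, the transcription factors stabilised by low oxygen, were shifted upward. Of 36 measured targets, 5 rose and 0 fell (6 higher and 0 lower when adjusted over the list alone), with a median difference of 0.34. LDHA, a subunit of lactate dehydrogenase, rose by 1.18 ± 0.18 (limma, adjusted p = 0.00947) on its brightest probe set and passed on 1 of 3, and the mean of its probe sets differed by 0.42 without passing (adjusted p = 0.0665). EGLN3, a prolyl hydroxylase that marks these factors for degradation, rose by 1.46 ± 0.29 (adjusted p = 0.0248), and the glycolytic enzyme PGK1 rose by 0.50 ± 0.11. P4HA1 and P4HA2 are members of this list too. EGLN3 and PGK1 passed in 5 and 2 of the 10 fits that left out a calf, and PGK1 did not pass with quantile normalization (adjusted p = 0.0534). VEGFA, the endothelial growth factor, differed by 0.39 ± 0.17 without passing (adjusted p = 0.262), and its other probe set differed by 0.80 (adjusted p = 0.0651). The list passed camera (adjusted p = 0.00104), with adjusted p = 0.641 with an estimated correlation. Hypoxia calf 199 had a list mean of 8.93 against 8.22 to 8.32 in the other hypoxia calves, and without it the median was 0.16 (camera adjusted p = 0.0157).

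Among 32 measured glycolysis genes, LDHA and PGK1 rose and 0 fell, and the same number passed when adjusted over the list alone. The muscle phosphoglycerate mutase PGAM2 differed by -0.39 ± 0.11 without passing (limma, adjusted p = 0.0947). The median was 0.14, and the list passed camera narrowly (adjusted p = 0.0404), with adjusted p = 0.641 with an estimated correlation. The call ended with quantile normalization (adjusted p = 0.0541), with the block of calf numbers (adjusted p = 0.192) and without control calf 176, 177, 180 or 181 or hypoxia calf 173, 192 or 204 (highest adjusted p = 0.121, without control calf 181, where the median was 0.06).

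Genes of the fetal cardiac programme were shifted upward, although ACTA1 and NPPA varied between calves and did not pass. Of 12 measured genes, 2 rose and 0 fell (5 higher and 0 lower when adjusted over the list alone), with a median difference of 0.49. FHL1, a LIM domain protein of the sarcomere, rose by 0.93 ± 0.14 (limma, adjusted p = 0.00931), and ANKRD1, a stretch-responsive ankyrin repeat protein, rose by 0.49 ± 0.10 on the brighter of 2 passing probe sets, although this call was kept in only 2 of the 10 fits that left out a calf. ACTA1, skeletal muscle alpha-actin, differed by 2.47 ± 0.61 (5.54-fold; 95% interval 1.13 to 3.81) and did not pass (adjusted p = 0.0572). It was 8.54 in control calf 177 and 11.5 to 12.8 in the other controls, and without that calf it differed by 1.78 and passed (adjusted p = 0.0134). ACTA1 passed in 2 of the 10 fits that left out a calf, that one among them. NPPA, the gene of atrial natriuretic peptide, differed by 2.13 ± 0.63 (adjusted p = 0.0980), with 12.9 in hypoxia calf 199 and 9.89 to 10.6 in the other hypoxia calves. The mean of 5 atrial, conduction and great vessel markers, NPPA among them, was 0.65 higher in hypoxia (exact permutation p = 0.00794). Without NPPA the mean of the other 4 was 0.28 higher (exact permutation p = 0.127). The list of 12 fetal cardiac genes passed camera (adjusted p = 4.00e-04), with adjusted p = 0.327 with an estimated correlation.

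Adult contractile genes had small differences, with list means of 12.6 in controls and 12.8 in hypoxia, a bright range where differences can be compressed. Of 18 measured genes, DES, the muscle intermediate filament desmin, rose by 0.52 ± 0.10 (limma, adjusted p = 0.0209) and MYPN, a Z-disc protein, by 1.06 ± 0.20, and 0 fell (4 higher and 0 lower when adjusted over the list alone). The call on DES ended without control calf 181 and that on MYPN without control calf 177 or 181 (highest adjusted p = 0.0585 and 0.0555). MYH7, the slow myosin heavy chain, differed by 0.05 ± 0.09 on its brightest probe set, whose mean of 14.2 lay near the highest value of 14.4 on any array. A dimmer MYH7 probe set fell by 0.69 (adjusted p = 0.0371). ATP2A2, the calcium pump of the sarcoplasmic reticulum, differed by -0.10 ± 0.09 (adjusted p = 0.631). The list had a median of 0.08 and passed camera (adjusted p = 0.0404), with adjusted p = 0.641 with an estimated correlation. The call ended with median centring (adjusted p = 0.0553), with quantile normalization (adjusted p = 0.116) and without control calf 176 or 180 or hypoxia calf 173, 178, 192 or 204 (highest adjusted p = 0.103). None of 19 measured genes of calcium handling and ion channels passed, over all probe sets or adjusted over the list alone, and that list did not pass (camera adjusted p = 0.633).

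HSPB6, a small heat shock protein of muscle, rose by 1.97 ± 0.21 (3.91-fold; limma, adjusted p = 0.00245) and passed with each calf left out in turn. It was the only gene of 18 measured in the heat shock list to pass over all probe sets, and 3 were higher and 0 lower when adjusted over the list alone. CRYAB and HSPB1, related small heat shock proteins, differed by 0.48 ± 0.14 and 0.42 ± 0.12 without passing over all probe sets. The list passed camera (adjusted p = 0.0401), with adjusted p = 0.641 with an estimated correlation. The call ended with quantile normalization (adjusted p = 0.0593), array weights (adjusted p = 0.0847), the block of calf numbers (adjusted p = 0.380) and without control calf 176, 177 or 180 or hypoxia calf 199 (highest adjusted p = 0.157, where the median went from 0.15 to 0.04).

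Genes of cholesterol synthesis and uptake were shifted upward. Of 18 measured genes, 3 rose and 0 fell (4 higher and 0 lower when adjusted over the list alone), with a median difference of 0.31. SQLE and CYP51A1, enzymes of sterol synthesis, rose by 1.46 ± 0.30 (limma, adjusted p = 0.0282) and 1.53 ± 0.32, and INSIG1, a sterol sensor that holds back this pathway, rose by 1.55 ± 0.35. HMGCS1, an earlier enzyme of the pathway, differed by 1.06 ± 0.28 without passing (adjusted p = 0.0710). As a set these transcripts passed camera (adjusted p = 0.0120), with adjusted p = 0.641 with an estimated correlation. The call ended without control calf 176 (adjusted p = 0.0631) and without hypoxia calf 173 (adjusted p = 0.0518), and SQLE, CYP51A1 and INSIG1 passed in 3, 3 and 1 of the 10 fits that left out a calf.

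Transcripts of cytosolic ribosomal proteins had small differences, nearly all of the same sign. None of 61 measured genes passed over all probe sets or adjusted over the list alone, yet 59 of 61 differences were negative, with a median of -0.16. RPL29 and RPS3 differed by -0.36 ± 0.09 and -0.31 ± 0.08 (limma, adjusted p = 0.0638 and 0.0751). The list passed camera (adjusted p = 3.24e-08), with adjusted p = 0.641 with an estimated correlation. The direction held with median centring and with quantile normalization.

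**Figure D2:**
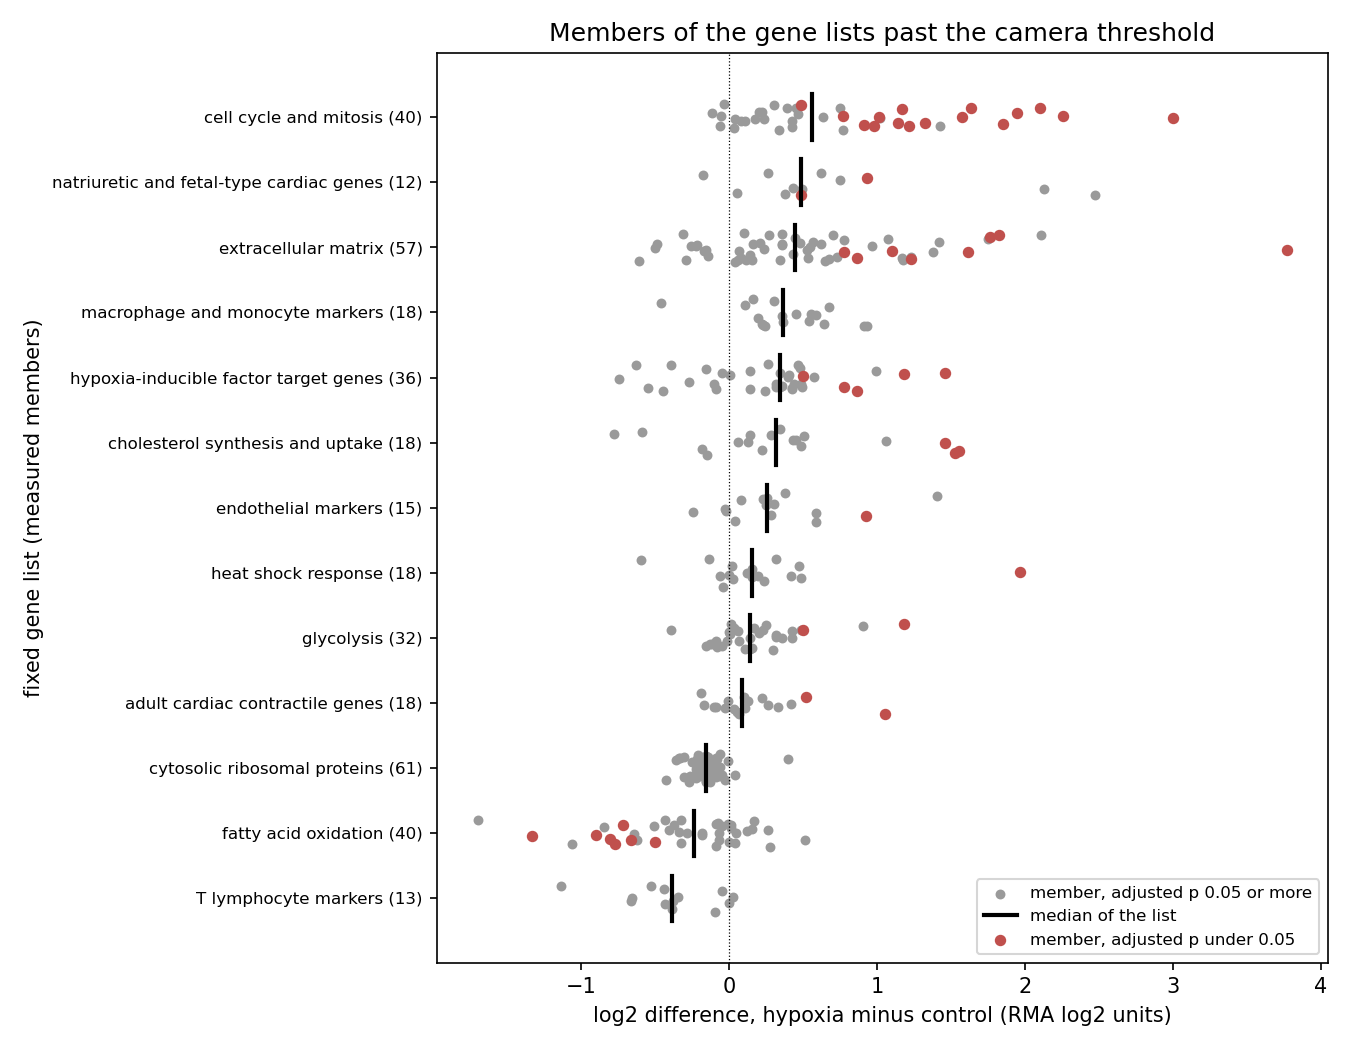
Log2 difference, hypoxia minus control, of every measured member of the 13 gene lists that passed camera with a preset correlation, 1 point per gene, with red points for genes that passed over all probe sets and a black line for each list's median. Medians ran from -0.39 for T lymphocyte markers to 0.56 for cell cycle genes; median centring, quantile normalization or both ended the calls on the glycolysis, heat shock and adult contractile lists.

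Markers of the cell types in the tissue moved in different directions. Markers of cardiomyocytes, the muscle cells of the heart, had list means of 13.45 ± 0.06 (SD) in controls and 13.49 ± 0.09 in hypoxia, a difference of 0.04 (exact two-sided permutation test, p = 0.381), and 0 of 13 passed over all probe sets or adjusted over the list alone. Of 15 endothelial markers, the water channel AQP1 rose by 0.93 ± 0.20 (limma, adjusted p = 0.0317) and 0 fell (3 higher and 0 lower when adjusted over the list alone). AQP1 passed in 3 of the 10 fits that left out a calf and did not pass with the mean of its probe sets (0.57, adjusted p = 0.111). The endothelial list passed camera (adjusted p = 0.00330), with adjusted p = 0.641 with an estimated correlation. Its list mean was 0.33 higher in hypoxia (exact permutation p = 0.0476, adjusted p = 0.25 over 21 measures). None of 18 macrophage and monocyte markers passed, over all probe sets or adjusted over the list alone, but 17 differences were positive, with a median of 0.36. That list passed camera (adjusted p = 0.00104), with adjusted p = 0.641 with an estimated correlation, and the call ended without hypoxia calves 178 and 199 (median 0.14, adjusted p = 0.186) and with array weights (adjusted p = 0.0780). None of 13 T lymphocyte markers passed over all probe sets, and 7 were lower and 0 higher when adjusted over the list alone. CD8A, a subunit of the co-receptor of cytotoxic T cells, differed by -1.14 ± 0.34 (adjusted p = 0.102). The T lymphocyte list had a median of -0.39 and passed camera (adjusted p = 0.00128), with adjusted p = 0.641 with an estimated correlation. Its mean was 5.53 in control calf 176 and 4.97 to 5.08 in the other controls, and without that calf the difference was -0.29 (exact permutation test over 126 assignments, p = 0.0159). Among the 15 cell type lists the atrial, conduction and great vessel markers had the largest difference in list mean, from 6.46 ± 0.31 (SD) in controls to 7.11 ± 0.47 in hypoxia (exact permutation p = 0.00794, adjusted p = 0.0556 over 21 measures), with every hypoxia calf above every control calf. None of the 5 passed over all probe sets, NPPA alone was higher when adjusted over the list, and the list did not pass (camera adjusted p = 0.116). Without NPPA the mean of the other 4 was 0.28 higher (exact permutation p = 0.127). Of 9 adipocyte markers, AGPAT2, an enzyme of triglyceride and phospholipid synthesis, fell by 0.48 ± 0.11 (adjusted p = 0.0404) and 0 rose, the same as when adjusted over the list alone, and AGPAT2 passed in 1 of the 10 fits that left out a calf and did not pass with another variance model (adjusted p = 0.0563). The adipocyte list had a median of -0.48 and did not pass (camera adjusted p = 0.116). Its mean was 7.16 in control calf 195 and 5.54 to 6.08 in the other controls, and without that calf the median was -0.09 (adjusted p = 0.506), but the list passed without control calf 176 (adjusted p = 0.0496) and with the block of calf numbers (adjusted p = 0.0117).

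Inflammatory gene groups did not pass as lists. CXCL10 was the only one of 31 measured interferon response genes to pass, over all probe sets and adjusted over the list alone. The median of that list was 0.04 (camera adjusted p = 0.416). Control calf 180 had an interferon list mean of 7.72 against 5.74 to 6.28 in the other controls and 6.26 to 6.59 in hypoxia, and without it the median was 0.40 and the list passed (adjusted p = 3.36e-07, against up to 0.970 with another calf left out). Of 23 complement genes, C1R, the protease that starts the classical pathway, fell by 0.89 ± 0.18 (limma, adjusted p = 0.0277) and 0 rose (1 higher and 1 lower when adjusted over the list alone); the call on C1R was kept in 4 of the 10 fits that left out a calf. The complement list did not pass (camera adjusted p = 0.128), but it passed without control calf 181 (adjusted p = 0.0461), without hypoxia calf 192 (adjusted p = 0.0148) and with the block of calf numbers (adjusted p = 0.00599). None of 37 acute inflammation genes passed over all probe sets (2 higher and 1 lower when adjusted over the list alone), with IL18 at 1.33 ± 0.32 (adjusted p = 0.0518), and that list passed only without hypoxia calf 192 among single calves left out (adjusted p = 0.0247). None of 30 antioxidant genes passed over all probe sets or adjusted over the list alone, although the metal-binding metallothionein MT1A differed by 3.38 ± 0.93 (adjusted p = 0.0801), with an SD of 2.40 among hypoxia calves. The list of adrenergic, angiotensin, endothelin and cGMP signalling did not pass (camera adjusted p = 0.511). Of its 25 genes GUCY1B1, a subunit of the nitric oxide receptor guanylate cyclase, rose by 0.58 ± 0.11 (adjusted p = 0.0242), and 2 were higher and 1 lower when adjusted over the list alone; GUCY1B1 passed in 7 of the 10 fits that left out a calf.

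Of the 40 lists, 13 passed camera with a preset correlation, 10 higher and 3 lower in hypoxia, and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05. The set test fry passed 3, the cell cycle, fetal cardiac and adult contractile lists. Several lists share genes, among them LDHA, PGK1, P4HA1 and P4HA2, so the calls are not independent.

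RNA quality was read from control probe sets placed along 6 transcripts. For 5 of them the 3' minus 5' value differed between groups by -0.06 to -0.31, and 0 of these differences passed an exact two-sided permutation test (lowest p = 0.143). For actin this value was 3.47 ± 0.57 (SD) in controls and 1.97 ± 0.42 in hypoxia (exact permutation p = 0.00794, adjusted p = 0.0556 over 21 measures of quality and cell content). The 3' actin probe set lay between 13.8 and 14.3 in hypoxia, near the highest value of 14.4 on any tested probe set. Compression at that end could by itself lower the actin 3' minus 5' value when actin rises. The actin control probe sets themselves were higher in hypoxia, from 8.59 ± 1.83 (SD) to 12.2 ± 0.65 at the 5' end, from 9.88 ± 1.95 to 13.2 ± 0.50 in the middle and from 12.1 ± 1.35 to 14.1 ± 0.23 at the 3' end. Control calf 177 had the highest 3' minus 5' value of all calves for actin, gapd, ef1a, Cyph and eIF.4E. These values were 4.35, 0.60, -1.55, 1.98 and 5.05, whereas its GST value of 1.28 was not the highest. Poorer RNA may therefore bear on the low actin and ACTA1 values of this calf and on the counts without it, which was not tested. The 3' actin probe set was low in this calf too, at 9.77 against 12.3 to 13.4 in the other controls. A loss of signal at the 5' end alone would not give that. The 3' gapd value of this calf was 13.6, against 13.3 to 13.6 in the other controls.

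**Figure D3:**
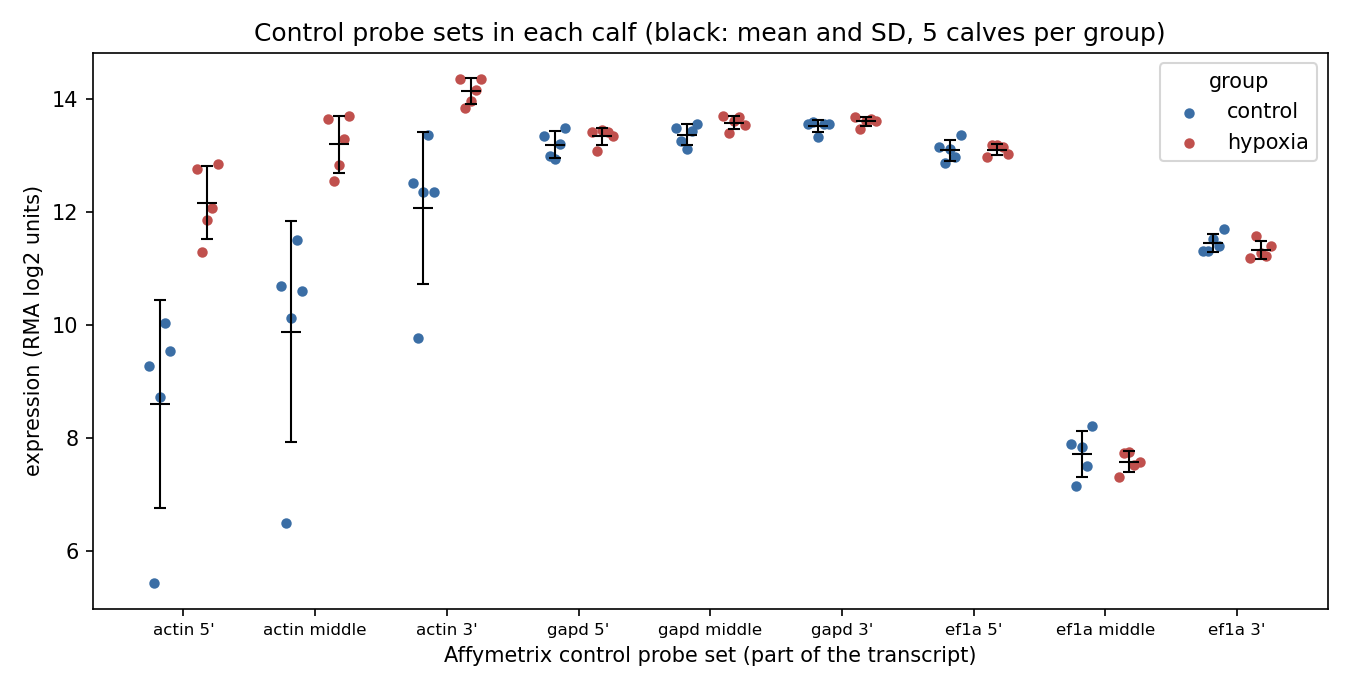
Control probe sets for actin, gapd and ef1a at the 5' end, middle and 3' end of each transcript, in RMA log2 units, with blue points for 5 control calves, red points for 5 hypoxia calves and black bars for the mean and SD. The middle actin probe set lay between 6.49 and 11.5 in controls and between 12.5 and 13.7 in hypoxia, whereas the 3' gapd probe set lay between 13.3 and 13.7 in all calves.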

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

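The tests on the actin control probe sets and on cell content were chosen after the results were seen; the count over other splits of the calves was planned before.

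The actin control probe sets lie outside the comparison of genes, and they were among the highest differences on the array, with 2.06 at the 3' end, 3.32 in the middle and 3.56 at the 5' end (each exact permutation p = 0.00794). Better preserved RNA in hypoxia would lower the 3' minus 5' value of other transcripts too. Over the other 5 transcripts it differed by -0.14 on average, against -1.50 for actin. The SE of 0.05 was taken over these transcripts and holds no spread between calves. Each of the 5 differed in the direction of better preservation, from -0.06 to -0.31, so preservation as part of the cause is not excluded. The larger actin value argues against preservation as the whole cause only if compression at the 3' end did not add to it. If the probe sets read ACTB, cytoplasmic beta-actin, its own probe set would differ as much, and the upper 95% bound of that difference was 0.55. All 3 control differences lay within the 95% interval of ACTA1, skeletal muscle alpha-actin (1.13 to 3.81), and control calf 177 was lowest in both, with 6.49 on the middle control probe set and 8.54 on ACTA1. That calf also had the highest 3' minus 5' values on most control transcripts, so its low values do not separate a shared transcript from poorer RNA. The other controls rose in the order 181, 180, 176 and 195 on both, from 11.5 to 12.8 on ACTA1 and from 10.1 to 11.5 on the middle control probe set. Hypoxia calves 178, 192 and 199 were the lowest of their group on both, in that order. Calves 173 and 204 were the highest on both, in opposite order. A candidate explanation is that the actin control probe sets detect ACTA1 or a close relative in heart tissue. It stays a hypothesis because probe sequences were not analysed here. If it holds, the actin ratio is no measure of RNA quality in this tissue.

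The lists of cell cycle, endothelial and macrophage genes passed camera upward at the preset correlation but not at an estimated one (adjusted p = 0.337, 0.641 and 0.641). A lower share of cardiomyocyte RNA would by itself raise the markers of every other cell type alike. Endothelial and T lymphocyte markers moved apart by 0.73 between groups (exact permutation p = 0.00794, and 0.60 with p = 0.0159 without control calf 176). The T lymphocyte list was dim, with means of 5.12 in controls and 4.73 in hypoxia. This pair was chosen after its lists were seen to move in opposite directions, so its p-value carries little weight. T lymphocytes could also have become fewer while the share of cardiomyocyte RNA fell, so a lower share stays open. Cardiomyocyte markers lie near the top of the array's range and were not used to judge it. More macrophages in the hypoxia samples could account for part of the pattern, and this stays open, since the macrophage list mean was 0.39 higher with an exact permutation p of 0.135. Hypoxia itself, load on the right ventricle, more endothelial cells and division of any resident cell stay open too. They cannot be separated in bulk tissue. No measure of load was used here, and low oxygen and any load it caused fell on the same calves.

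Other divisions of the calves gave far fewer probe sets that passed. Among 100 of the 126 splits of the calves into 5 and 5, 1 gave as many as 652, the real one, and the highest of the others gave 4. Every other split mixes control and hypoxia calves, so a difference between the groups adds to the spread within it and lowers its count. Such counts are not those expected without any difference. The splits also do not address the uneven runs of calf numbers, where 217 probe sets passed with the run as a block.

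Of 322 groups of 5 calves examined for a calf far from the rest, 19 had one, where chance gives about 16.1. In hypoxia calf 199, NPPA was 12.9, RGS5 was 10.6, and the list means of atrial and conduction markers, fetal cardiac genes, hypoxia-inducible factor targets and mitochondrial biogenesis genes were 7.95, 10.5, 8.93 and 9.35, the last lower than in the other hypoxia calves and the rest higher. In hypoxia calf 178, HMGCS1 was high at 11.3, the Schwann cell list high at 5.49 and NDUFB7 low at 10.8. In hypoxia calf 204, UCP2 was high at 5.84 and the list of adrenergic and related signalling high at 6.81. In control calf 195, the sterol genes CYP51A1 and INSIG1 were high at 7.98 and 6.40, as was ASPH at 4.82. In control calf 177, IL1RN and MFAP4 were low at 4.94 and 6.50, and in control calf 181 CKM was low at 12.7. The T lymphocyte list was high in control calf 176 at 5.53, and the interferon list was high in control calf 180 at 7.72.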

How the results depend on the processing

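The fits without hypoxia calves 178 and 199 together and within each run of calf numbers were chosen after the data were seen; the other alternatives were planned. The count of probe sets that passed stayed within 1.5 times of 652 with median centring, quantile normalization, a filter on dim probe sets, another variance model and array weights (624 to 756). It was 0 (0 higher, 0 lower, 0 genes) with Welch's test, where the smallest adjusted p was 0.0589 and all 652 kept an unadjusted p under 0.05. The block for the run of calf numbers gave 217 (152 higher, 65 lower, 114 genes), 197 of them among the 652. An adjusted p of 0.10 gave 1436 (789 higher, 647 lower), and a fold of at least 1.5 left 160 lower. Leaving out 1 calf gave 241 to 605 probe sets (167 to 383 higher, 74 to 222 lower) and 127 to 318 genes. Without hypoxia calves 178 and 199 the counts were 155 (116 higher, 39 lower, 83 genes), in the lower run of calf numbers 31 (26 higher, 5 lower, 19 genes) and in the upper run, with 1 control calf assumed to vary like the hypoxia calves, 0 (0 higher, 0 lower, 0 genes). The fits on fewer calves have fewer samples, and for the other changes the cause was not tested.

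Lists that passed numbered 0 with an estimated correlation, 3 with fry and 10 to 15 under the other alternatives. The cell cycle, extracellular matrix, fatty acid oxidation, fetal cardiac, ribosomal, hypoxia-inducible factor, endothelial, macrophage and T lymphocyte lists passed with each calf left out. In the lower run of calf numbers the hypoxia-inducible factor and endothelial lists did not pass (adjusted p = 0.193 and 0.105), nor in the upper run the T lymphocyte and ribosomal lists (adjusted p = 0.134 and 0.544). Control calf 195 is the only control in the upper run, so the values there cannot be told apart from what is particular to that calf and neither support nor weaken a result. Of 115 named genes, 50 passed, and 27 of these passed with each calf left out; the block for the run of calf numbers ended 22 of the 50 calls. None of these 50 genes and none of the 13 lists that passed changed sign under any alternative that was planned; genes outside the naming rule, those chosen after their values were seen among them, were not followed through the alternatives. In the upper run INSIG1 (-0.14), the cholesterol list (-0.027) and the adult contractile list (-0.0049) did, against control calf 195 alone, in which INSIG1 was 6.40 and outlying among the controls. Among results that did not pass, MYH7 was -0.27 and CKM 0.20 with the mean of all probe sets, ATP2A2 and SLN were 0.011 and -0.030 in the lower run, and ASPH, SLC16A1 and CIDEA were -0.060, -0.14 and -0.095 in the upper run. With 1 calf left out, COL1A1 ran from -0.045 to 0.27, and medians ran from -0.048 to 0.17 for fibroblast markers, -0.047 to 0.060 for antioxidant genes and -0.11 to 0.40 for interferon genes. The antioxidant median was -0.0010 with quantile normalization, and the interferon median was -0.14 in the lower run. The acute inflammation median was -0.060 without hypoxia calves 178 and 199 and -0.014 in the upper run. The calcium handling median was -0.0036 with the filter, -0.027 with the block, -0.052 over bright members and -0.048 in the upper run, where the cardiomyocyte median was -0.0064. The cause of these sign changes was not tested.

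The deposited tables were equal in every shared cell, no probe set with several symbols was named, and Welch's test gives no list test, so those alternatives had nothing to compare. No paired analysis was possible because the groups share no calf numbers. Signal near the top of the range limits what can be said of MYH7. The same holds for ATP2A2, with means of 13.7 in controls and 13.6 in hypoxia, and for ACTA1 in hypoxia, with a mean of 13.8. It may hold in part for the bright adult contractile and oxidative phosphorylation lists. Dim probe sets were left out in an alternative that passed 14 lists and list members below the median of all probe sets in another that passed 12.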

Other observations

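The genes named here were chosen after their values were seen, and the tests of the clock and imprinted gene lists were written down before their results were seen, for patterns noticed in the data.

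Several genes of the cytoskeleton and the Z-disc, the anchor of the sarcomere's thin filaments, were among the increases outside the fixed lists. The intermediate filament gene NES rose by 1.77 ± 0.26 (limma, adjusted p = 0.00931) and the tropomyosin TPM3 by 0.89 ± 0.12, and each passed on 2 of 2 probe sets. MYOT, a Z-disc protein, rose by 1.33 ± 0.19, the actin cross-linkers FLNC and ACTN1 by 0.99 ± 0.20 and 1.27 ± 0.19, and DYSF, a protein of membrane repair, by 1.01 ± 0.17. NEB, known as a thin filament protein of skeletal muscle, rose by 1.35 ± 0.19 from a low level of 4.46. NEB and ACTN1 each passed on 1 of 3 probe sets. CKB, the brain type of creatine kinase, rose by 1.41 ± 0.18 (adjusted p = 0.00473), and CD44, a receptor of hyaluronan and osteopontin, by 1.62 ± 0.32. No enrichment of this group was tested.

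Among metabolic genes outside the lists, PPIP5K2, an inositol pyrophosphate kinase, rose by 1.37 ± 0.14 (limma, adjusted p = 0.00245, passing on 4 of 4 probe sets), and PPM1K, the phosphatase that activates breakdown of branched-chain amino acids, rose by 1.39 ± 0.20, passing on 3 of 4. COQ8A, needed for coenzyme Q synthesis, fell by 0.91 ± 0.12 and G0S2, an inhibitor of fat breakdown, by 1.27 ± 0.26. RAMP1, a subunit of the receptor for calcitonin gene-related peptide, fell by 1.39 ± 0.25 (adjusted p = 0.0167, passing on 2 of 2 probe sets).

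The small shift of ribosomal protein genes was set against other bright genes. The 111 other genes of the same brightness had a median difference of -0.01 against -0.16 for the ribosomal list. This does not allow for the correlation of ribosomal genes with each other, and camera gave the list an adjusted p = 0.641 with an estimated correlation.

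The circadian clock gene HLF fell by 0.88 ± 0.21 in hypoxia (limma, adjusted p = 0.0475, passing on 2 of 2 probe sets), and PER2, another clock gene, differed by -1.32 ± 0.39 on its brighter probe set (adjusted p = 0.0952) and passed on 1 of 2. Collection of tissue at another time of day could give this, and other clock genes that peak at opposite times would then move apart. The difference between them, over 3 named genes (NFIL3 and CRY1 against NR1D1), was -0.25, opposite in sign to that prediction. NFIL3 and CRY1, taken to peak together, differed by 0.33 and -0.42, and NR1D1 by 0.20. Because NFIL3 and CRY1 moved apart, the sign of their mean against NR1D1 decides little. The rule written beforehand counted any difference that was not positive against the hypothesis, and this was met. The difference was not beyond the spread between calves (exact permutation p = 0.159), so the hypothesis is not excluded.

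DLK1, an imprinted gene of fetal growth, fell by 1.14 ± 0.21 (limma, adjusted p = 0.0190, passing on 2 of 2 probe sets), and the fetal growth regulator GPC3 fell by 1.11 ± 0.23. The hypothesis that imprinted growth genes fell together was not borne out, although it cannot be excluded: the mean over 13 other imprinted genes differed by 0.017 (exact permutation p = 0.786), with PEG3 at -0.93 and MEST at 0.78. The rule written beforehand counted any mean that was not below that of controls against this hypothesis, and this was met.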
